A study of Mus musculus with 12 samples.

How the data were processed

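RNA was measured in 12 libraries of primary mouse vascular smooth muscle cells from the aorta, in 4 groups of 3: wild type (WT) and NR4A3 knockout (KO) cells at day 1 and at day 14 of culture. Per the labels' protocols, total RNA was taken with TRIzol, libraries were made with the NEBNext Ultra RNA kit, and the medium of all groups held 10 mM beta-glycerophosphate (beta-GP). The treatment label reads none for WT and beta-GP for KO, so a contrast of genotype also holds whatever that difference in labels stands for. Nothing in the labels says that the 3 replicates of a group are separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

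The deposited values are raw read counts per gene name, in 1 table for each day, with whole numbers in every library. The submitters' processing notes name the genome build mm9. The aligner, the counting tool, the gene annotation and the use of strand are not given in the sources used here, so reads of overlapping or near-identical genes cannot be assigned with certainty. The columns of each table carry a genotype and a replicate number, with CTR read as WT, and the day was taken from the table. The tables held 28494 lines (day 1) and 30866 lines (day 14). Lines repeating a name with identical counts were removed (43 and 53), which left 28451 and 30813, of which 26732 names were in both tables. Across the tables, 26 names had been turned into dates and 2 names occurred with different counts. Of the names, 98.2% and 98.1% matched the GENCODE M21 gene names. Library totals ranged from 13848199 to 30105118 counts. Neighbouring genes were taken from the order in the RefSeq table of assembly GRCm38.p6, which differs from the build of the counts, so no positions are given.

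Counts were analysed with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr on the groups in the fit, quasi-likelihood F test, Benjamini-Hochberg adjustment over the genes tested, called at an adjusted p below 0.05). KO was compared with WT at each day in a fit of that day's 6 libraries. The change of the KO effect between the days, and day 14 against day 1 within each genotype, came from 1 fit of all 12 libraries over the shared names. The 2 days come from separate tables, so day and table (a possible batch) cannot be told apart in the contrasts between days. A shift common to a table cancels in the difference of the KO effects. Values are given as CPM (counts relative to the scaled library total, from the same fit), as mean ± SD of 3 libraries, and as log2 fold changes ± standard error, the latter computed as the fold change over the square root of F. Folds against a group with 0 counts are lower bounds against 3 counts over the group. With 1 to 3 counts in a group the ratio of counts is given with its exact 95% binomial interval, which covers counting error only.

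Before the data were examined, 26 gene lists were fixed for the tissue and treatment, among them 6 of markers of other cell types. Lists with 5 or more tested members were compared with the other genes by camera (limma 3.58.1, preset correlation 0.01, adjusted over the lists of a comparison). Camera with an estimated correlation and fry were alternatives. For the sex-linked list only counts are given. In the fits of all libraries, the lists whose mean, median and test differed in sign were all without a call. The genes named were also chosen by a rule written beforehand. It takes Nr4a3, and the 6 largest rises and 6 largest falls of each KO against WT comparison (4 and 4 elsewhere) among genes with an adjusted p below 0.05, a mean log2 CPM of at least 3 and groups that do not overlap (no such overlap rule for the change of the KO effect). It adds 17 genes of calcification, smooth muscle and glycolysis whatever their result, and up to 2 rising and 2 falling members of each list with a called change. Predicted genes were passed over, and some genes that the rule takes are not reported here, though they stay in the tests and counts. Genes of the 17 without a tested value in a comparison are not analysed there. Nr4a1 and the genes around Yap1 are outside the rule and were chosen after their values were seen.

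The alternatives tried were size factors of the DESeq2 kind, library size alone, DESeq2 1.42.0 or limma-voom as the test, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, other sets of libraries in the fit, leaving out each library, and, added after the data were seen, leaving out shifted runs of neighbouring genes. Each test was first tested on counts simulated from the real means and library sizes. With 4-fold changes, 100% of the changed genes were recovered for KO against WT at day 1, 92.4% at day 14, 77.3% for the change of the KO effect, and 84.8% for each contrast between days. With 2-fold changes the shares were 70.1%, 76.1%, 56.7%, 71.6% and 67.2%. With 1.5-fold changes they were 65.7%, 28.4%, 20.9%, 49.3% and 35.8%. Of the calls, 4.85%, 5.07%, 7.21%, 5.52% and 3.85% were of unchanged genes, and 0 of 40 unchanged lists was called in any comparison. The simulated genes varied independently, whereas the estimated correlation within the real lists reached 0.818 (cholesterol synthesis, KO against WT at day 14). The lists simulated therefore say nothing on false calls of correlated lists. Only 67, 67 and 66 genes were changed at 1.5-, 2- and 4-fold, far fewer than were called in the data.

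For runs of neighbours, the medians of blocks of 15 genes in order along the chromosomes were set against 1000 shuffled gene orders. On simulated values with noise of SD 0.6 (log2) between genes, this found the 4 blocks planted with opposite signs at the 2 days and the 3 planted with the same sign. With noise of SD 1.0 it found 8 and 7 (and 10 with none planted), and the 8 lie below the 12 blocks of opposite sign that shuffled orders reached, so planted blocks could not be told from chance at that noise. The smaller noise was added after the first simulation. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and figures.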

Results

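RNA was sequenced from primary aortic vascular smooth muscle cells of mice, wild type (WT) or with a knockout (KO) of NR4A3, a nuclear receptor of the NR4A family. The question was how the loss of this receptor changes gene expression in cells kept in a calcifying medium. Beta-GP, a phosphate donor, is used to drive mineral deposition in cultured smooth muscle cells. The protocols give it for all groups, but the treatment label for KO alone. A KO effect may therefore also hold an effect of the medium. Each of the 4 groups had 3 libraries. Library totals were 24929624 to 30105118 counts for WT and 17143281 to 20091307 for KO at day 1, and 13848199 to 19519654 for WT and 14369933 to 18797157 for KO at day 14. Replicates of every group differed by more than sampling noise (chi-square per gene from 2.91 to 51.5), and the values of 36.2 and 51.5 both involved WT replicate 1 of day 14. Mitochondrial transcripts took 4.39% ± 0.13 (SD, n = 3) of the counts in WT and 4.18% ± 0.52 in KO at day 1, and 3.34% ± 0.08 and 4.61% ± 0.19 at day 14.

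Nr4a3 itself was lower in the KO libraries at both days and was higher at day 14 than at day 1 in both genotypes. At day 1 it stood at 2.06 ± 0.233 CPM in KO and 4.20 ± 0.385 CPM in WT (mean ± SD, n = 3; log2 fold change -1.02 ± 0.21 SE, adjusted p = 8.55e-04), from 34 to 48 counts per KO library and 97 to 121 per WT library. At day 14 it stood at 49.9 ± 13.5 CPM in KO and 240.4 ± 19.9 CPM in WT (log2 fold change -2.27 ± 0.19, adjusted p = 2.60e-05), from 564 to 1011 and 3669 to 4765 counts. The fall in KO was larger at day 14, by -1.23 ± 0.29 on the log2 scale (adjusted p = 0.00181). Between the days Nr4a3 rose by 5.80 ± 0.19 in WT (adjusted p = 7.23e-12) and by 4.57 ± 0.20 in KO (adjusted p = 1.45e-10). Day and table (a possible batch) cannot be told apart in these rises. The labels do not state which part of the gene was removed, and reads remained in every KO library.

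**Figure D1:**
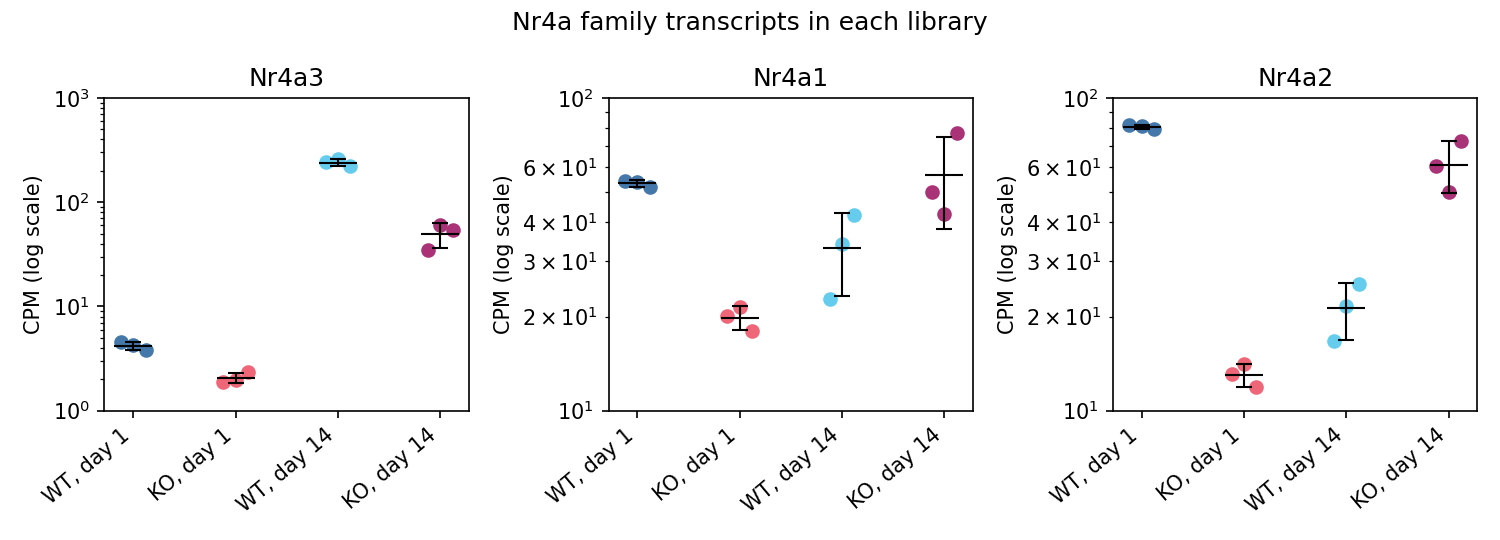
CPM of Nr4a3, Nr4a1 and Nr4a2 (log scale) in each of the 12 libraries by group; points are libraries and bars are means with SD. Nr4a3 was lower in KO than in WT at both days, whereas Nr4a1 and Nr4a2 were lower on average in KO at day 1 and higher at day 14.

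Across 15976 genes, the libraries of KO at day 1 were closest to those of WT at day 14. The correlation of log2 CPM between these groups had a median of 0.974 (0.962 to 0.981 over 9 pairs of libraries), against medians of 0.921 to 0.936 for the other pairs of groups and 0.975 to 0.994 within groups. The first principal component (47.5% of the variance) set KO at day 1 and WT at day 14 apart from WT at day 1 and KO at day 14, and the second (29.3%) set the latter groups apart from each other. In the fit over 12 libraries, 1562 genes differed between KO at day 1 and WT at day 14, and 8104 to 8762 between any other pair of groups. This comparison of all pairs was added after the data were seen.

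**Figure D2:**
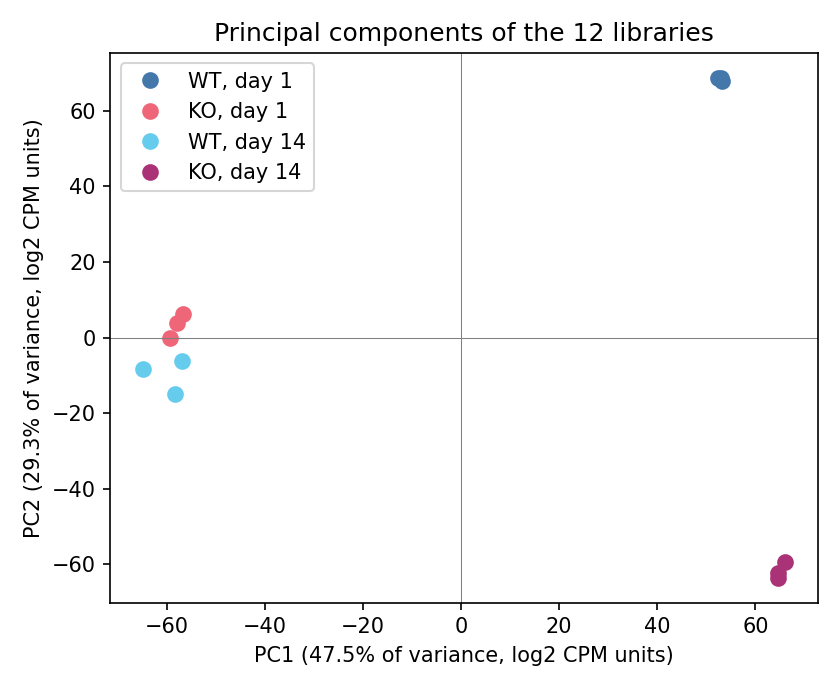
First and second principal components (47.5% and 29.3% of the variance) of log2 CPM over 15976 genes, 1 point per library, coloured by group. The KO libraries of day 1 lie beside the WT libraries of day 14.

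The resemblance included neighbouring genes on chromosome 9 around Yap1, a transcriptional coactivator of the Hippo pathway. Yap1 stood at 3775 ± 240 CPM in KO and 955 ± 37.9 CPM in WT at day 1 (SD, n = 3), and at 626 ± 32.0 CPM in KO and 4561 ± 331 CPM in WT at day 14. Birc2, an inhibitor of apoptosis, followed with 1633 ± 232 and 391 ± 4.70 CPM at day 1, and 186 ± 13.2 and 1578 ± 192 CPM at day 14, in KO and WT. Dcun1d5 went the same way. Of 20 tested genes in order from Pdgfd to Gm46102, 17 were higher in KO at day 1 and lower in KO at day 14, and the 3 others were the matrix metalloproteinases Mmp13, Mmp3 and Mmp8. Jrkl, the next gene, stood at 30.9 ± 7.94 and 24.6 ± 0.88 CPM at day 1, and at 24.7 ± 1.58 and 24.5 ± 1.31 CPM at day 14. These genes were chosen after their values were seen.

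**Figure D3:**
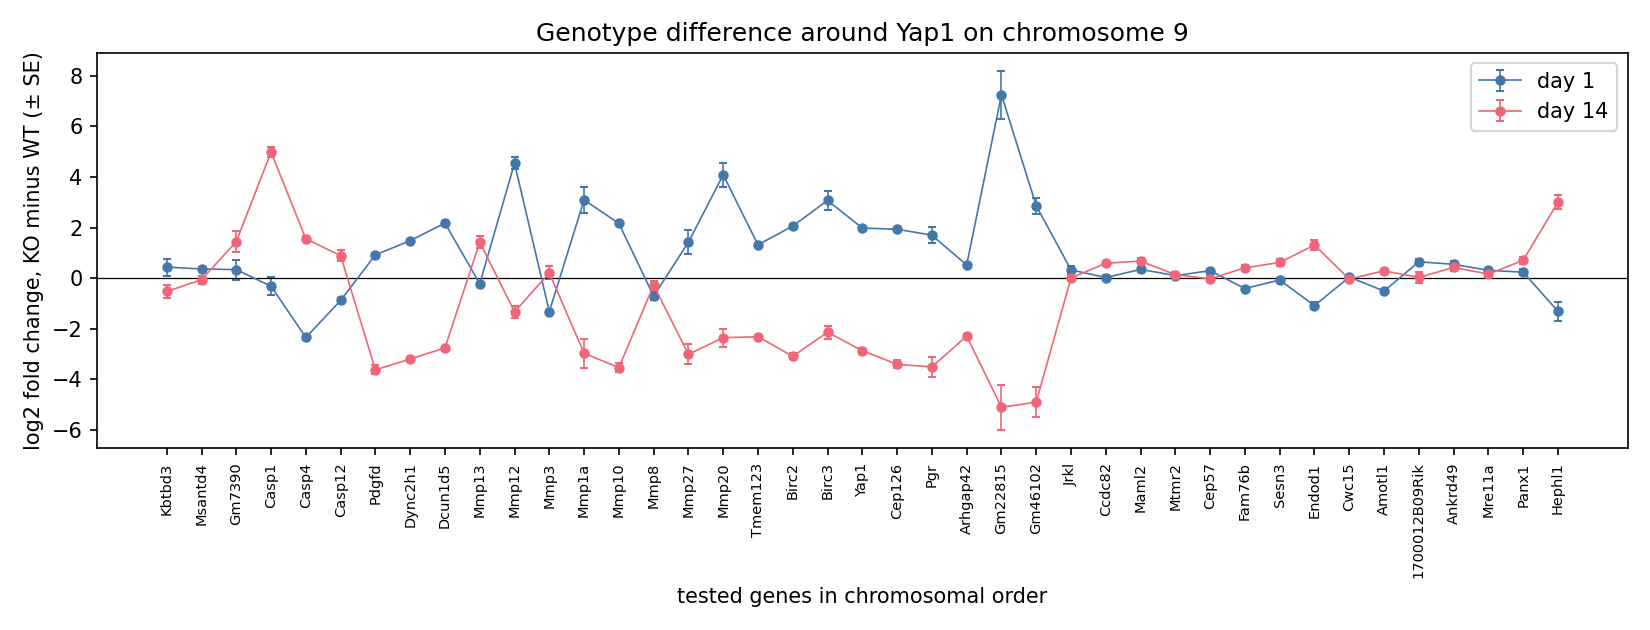
Log2 fold change of KO against WT (± SE) at day 1 and at day 14 for the genes around Yap1, in their order on chromosome 9 in the RefSeq table of GRCm38.p6. Yap1 was at 1.98 at day 1 and -2.87 at day 14, and Jrkl at 0.33 and 0.01.

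The comparison of KO with WT at day 1 asks how KO cells differ from WT early in culture, where the treatment label differs too. Genes of the antiviral interferon response were far higher in KO, and genes of cholesterol synthesis, glycolysis, the hypoxia response and the extracellular matrix were lower. Oas2 and Oas1a, synthetases that sense double-stranded RNA, stood at 25.2 ± 5.92 and 28.7 ± 5.63 CPM in KO (SD, n = 3). In WT Oas2 had 3 counts in all, a ratio of 650-fold (95% counting interval 222 to 3158), and Oas1a stood at 0.152 ± 0.0979 CPM, although reads of the closely similar Oas1 copies may be split. Lox, the enzyme that crosslinks collagen, fell from 924 ± 33.2 CPM in WT to 115 ± 17.6 CPM in KO. Fdps, which makes farnesyl diphosphate on the way to cholesterol, stood at 28.3 ± 0.726 CPM in WT and 1.47 ± 0.400 CPM in KO.

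In all, 9341 of 15368 genes differed at day 1 (edgeR, adjusted p below 0.05), 4705 higher and 4636 lower in KO, and 1551 and 1456 of them by at least 2-fold. The higher share was 50.4% with TMM scaling and 61.7% with library size alone, which shifts the median of all genes by 0.12 on the log2 scale. Among known genes with a mean log2 CPM of at least 3 and no overlap between the groups, the largest rises were those of Slc6a12, a betaine and GABA transporter (fitted 12.40 against 0 counts in WT, at least 787-fold higher), Oas2 (9.16), Rgs1, a regulator of G protein signalling (8.24 ± 0.28), Usp18, a protease of the interferon response (7.52 ± 0.31), Oas1a (7.50 ± 0.28) and Dthd1 (6.79 ± 0.25). Within the same limits, the largest falls were those of Scn7a, a sodium channel (-5.91 ± 0.24), Stc1, a secreted stanniocalcin (-5.59 ± 0.18), Rnf150 (-5.37 ± 0.25), Phex, a peptidase of phosphate balance (-5.16 ± 0.13), Apln, the ligand apelin (-4.92 ± 0.26), and Abca1, a cholesterol exporter (-4.78 ± 0.10). Their adjusted p ranged from 2.16e-12 to 4.64e-09.

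Of the 23 tested genes of the interferon response, 22 were higher in KO at day 1 and 0 lower (median log2 fold change 3.94, adjusted p = 1.85e-38, and adjusted p = 0.0153 with an estimated correlation). All 18 genes of cholesterol synthesis were lower (median log2 fold change -2.45, adjusted p = 1.91e-50, and adjusted p = 0.00206 with an estimated correlation), with Fdps among the largest falls (-4.27 ± 0.15). Of 24 genes of glycolysis and lactate, 20 were lower and 3 higher (median log2 fold change -1.35, adjusted p = 2.74e-17, and adjusted p = 0.0294 with an estimated correlation); the aldolase Aldoc (-3.55) and the pyruvate dehydrogenase kinase Pdk1 (-2.28) fell most, and Ldhb (0.99) and the hexokinase Hk2 (0.46) rose. Of 18 hypoxia genes 17 were lower and 0 higher (median log2 fold change -1.15, adjusted p = 4.62e-14, and adjusted p = 0.00816 with an estimated correlation), with Ankrd37 (-2.86) and Pdk1 in front. Of 27 matrix genes 20 were lower and 5 higher (median log2 fold change -1.09, adjusted p = 3.21e-17, and adjusted p = 0.00694 with an estimated correlation). Lox (-3.01 ± 0.09) and the collagen Col3a1 (-2.90 ± 0.06) fell most, while Postn, the matricellular periostin (5.02), and Col11a1 (1.00) rose.

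The other lists called at day 1 passed with the preset correlation and with fry, but not with an estimated correlation. Of 19 genes of inflammation and chemokines 13 were lower and 2 higher (median log2 fold change -1.12, adjusted p = 4.68e-05, and adjusted p = 0.0862 with an estimated correlation). The siderophore-binding Lcn2 (-6.96) and the nitric oxide synthase Nos2 (-5.33, and -10.11 without KO replicate 2) fell most, and the interleukin-1 antagonist Il1rn (1.44) and the chemokine Ccl5 (1.73) rose. Of 19 NR4A and immediate early genes 14 were lower and 5 higher (median log2 fold change -0.73, adjusted p = 0.00640, and adjusted p = 0.439 with an estimated correlation); Egr3 (-2.97) and Nr4a2 (-2.64) fell, and the phosphatase Dusp1 (1.64) and Myc (0.96) rose. Of 18 p53 and senescence genes 11 were higher and 3 lower (median log2 fold change 0.56, adjusted p = 4.37e-04, and adjusted p = 0.180 with an estimated correlation), with Phlda3 (1.88) and Aen (1.36) up and Sesn1 (-0.95) and Trp53 (-0.53) down. Of 22 genes of BMP and TGF-beta signalling 14 were higher and 5 lower (median log2 fold change 0.49, adjusted p = 0.00136, and adjusted p = 0.102 with an estimated correlation). Id4 (4.12) and Smad9 (3.73) rose, Ltbp1 (-1.13) fell, and the receptor Bmpr1b had 198 counts in WT and 1 in KO, a ratio of 144-fold (95% counting interval 25.5 to 5711; fitted log2 fold change -6.78). The mean of this list was 0.78, and 0.48 and 0.47 without KO replicates 2 and 3.

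Markers of other cell types also moved at day 1. Of 10 adventitial fibroblast markers 9 were lower and 1 higher in KO (median log2 fold change -1.07, adjusted p = 6.05e-05, and adjusted p = 0.189 with an estimated correlation). The complement inhibitor Serping1 (-5.02) and Cd248 (-3.25) fell most. Col14a1 rose (1.34, adjusted p = 0.0323) but did not pass without KO replicate 1 (0.0906) or 3 (0.121), or without WT replicate 1 (0.122) or 2 (0.146), nor with DESeq2 (0.105). Of 5 adipocyte markers 4 were higher and 0 lower (median log2 fold change 0.62, adjusted p = 0.00556, and adjusted p = 0.102 with an estimated correlation), with the fatty acid carrier Fabp4 (5.56) and the lipase Lpl (1.79) in front. No other list passed: members higher and lower numbered 9 and 5 of 17 for contractile smooth muscle, 4 and 6 of 18 for osteogenic and chondrogenic genes, 5 and 6 of 12 for calcification inhibitors, and 1 and 4 of 9 for phosphate handling. The numbers were 12 and 4 of 23 for oxidative phosphorylation, 2 and 5 of 13 for lactylation writers and erasers, 5 and 11 of 18 for matrix proteases, 6 and 12 of 28 for the cell cycle, 8 and 6 of 18 for endoplasmic reticulum stress, 8 and 4 of 14 for Wnt signalling and 2 and 2 of 5 for mesothelial markers. Endothelial, macrophage and Schwann cell markers had 3 tested members each, too few for a test. Contractile genes (0.0438) passed without KO replicate 2, as did calcification inhibitors (0.0315), whose test pointed down while their mean was 0.18, so no direction is given. Adjusted over the list alone, the counts of all these lists were the same, except 21 lower for glycolysis, 21 lower for the matrix and 9 higher for endoplasmic reticulum stress.

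Among the genes of calcification followed in every comparison, Alpl, the phosphatase that removes the mineral inhibitor pyrophosphate, had 3 counts in WT and stood at 11.9 ± 1.41 CPM in KO at day 1, a ratio of 312-fold (95% counting interval 106 to 1519; fitted log2 fold change 8.08, adjusted p = 7.12e-10). The homeobox gene Msx2 was also higher (2.57 ± 0.50, adjusted p = 5.88e-04). Runx2, the osteoblast transcription factor (-0.63 ± 0.07), the matrix protein osteopontin, Spp1 (-1.19 ± 0.10), and the inhibitors of mineral deposition Mgp (-2.54 ± 0.16) and Enpp1 (-1.22 ± 0.15) were lower (adjusted p at most 1.31e-05). The glycolytic genes Aldoa (-1.63 ± 0.06), Pfkl (-1.74 ± 0.06) and Ldha (-1.39 ± 0.11) were lower too. The contractile gene Acta2 was higher, with 663 ± 33.6 CPM in KO and 273 ± 18.8 CPM in WT (1.28 ± 0.06, adjusted p = 2.76e-09). Cnn1, below 1 CPM in both groups, passed at 1.49 ± 0.49 (adjusted p = 0.0176) but not without KO replicate 2 (0.0913) or without WT replicate 1 (0.0749), 2 (0.0563) or 3 (0.0584), nor with DESeq2 (0.0794) or without a filter (0.0523). Sox9 (0.38 ± 0.16, adjusted p = 0.0509), Tnfrsf11b (0.50 ± 0.24, 0.0887) and Phospho1 (0.84 ± 0.42, 0.0986) did not pass. They stood at 0.12 without KO replicate 2, 0.32 without KO replicate 1 and 0.56 without WT replicate 3. Without KO replicate 3, Sox9 (adjusted p = 0.00205) and Tnfrsf11b (0.0182) did, as did Sox9 with library size alone (0.0167) and other filters (0.00269 without a filter, 0.0487 with a stricter one). Tnfrsf11b also passed with library size alone (0.0405).

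The comparison of KO with WT at day 14 asks the same after long culture. Inflammatory genes were higher in KO: Lcn2 stood at 78.1 ± 41.4 CPM in KO and 0.773 ± 0.371 CPM in WT (SD, n = 3), and the eosinophil chemokine Ccl11 at 56.8 ± 6.18 and 0.697 ± 0.379 CPM. The gelatinase Mmp9 stood at 23.2 ± 4.71 CPM in KO and 0.185 ± 0.176 CPM in WT. Its list, of matrix proteases and inhibitors, had 7 higher and 7 lower of 20 and was not called. Genes of the p53 response were mostly lower, such as the receptor Eda2r with 53.3 ± 4.33 CPM in KO and 202 ± 12.7 CPM in WT. Of the matrix genes called, more were higher than lower, and Lox stood at 2279 ± 54.1 CPM in KO and 219 ± 90.6 CPM in WT, a direction opposite to that of day 1. With an estimated correlation none of the inflammation, p53 and matrix lists was called (adjusted p = 0.243, 0.243 and 0.850 with an estimated correlation).

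In all, 6918 of 14905 genes differed at day 14, 3388 higher and 3530 lower in KO, and 1294 and 1761 of them by at least 2-fold. The higher share was 49.0%, and 42.5% with library size alone. Among known genes with a mean log2 CPM of at least 3 and no overlap between the groups, the largest rises were those of Mmp9 (6.79 ± 0.41), Lcn2 (6.58 ± 0.47), Ccl11 (6.42 ± 0.25), the haemoglobin-binding haptoglobin Hp (6.08 ± 0.54), Clca2 (5.81 ± 0.32) and Mgp (5.13 ± 0.18). The largest falls within these limits were those of the interleukin receptor Il7r (-6.73 ± 0.28), the surface antigen Cd24a (-6.03 ± 0.23), the stathmin Stmn4 (-5.85 ± 0.24), Rgs1 (-5.72 ± 0.29), the peptide hormone Cck (-5.52 ± 0.20) and Ppargc1a, a coactivator of mitochondrial biogenesis (-5.40 ± 0.16). Their adjusted p ranged from 2.56e-07 to 3.98e-05. The spread between replicates was wider at day 14 (biological coefficient of variation 0.146) than at day 1 (0.0770), and 9209 genes passed without WT replicate 1.

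None of the lists called at day 14 kept its call with an estimated correlation. Of 18 genes of inflammation and chemokines 17 were higher in KO and 0 lower (median log2 fold change 2.58, adjusted p = 2.44e-28, and adjusted p = 0.243 with an estimated correlation). Of 18 p53 and senescence genes 15 were lower and 3 higher (median log2 fold change -1.16, adjusted p = 4.50e-07, and adjusted p = 0.243 with an estimated correlation). The antiproliferative Btg2 (-2.26) and Eda2r (-1.92) fell most, and the death receptor Fas (2.68) and Sesn1 (0.71) rose. Of 27 matrix genes 13 were higher and 4 lower (median log2 fold change 0.57, adjusted p = 4.15e-06, and adjusted p = 0.850 with an estimated correlation), with Lox (3.38) and Col6a2 (3.14) up and the collagens Col11a1 (-4.41) and Col1a1 (-1.59) down. Of 23 genes of glycolysis and lactate 11 were higher and 2 lower (median log2 fold change 0.32, adjusted p = 0.00517, and adjusted p = 0.850 with an estimated correlation); the glucose transporter Slc2a1 (1.45) and Pdk1 (1.41) rose, and Aldoc (-2.29) and Hk2 (-0.34) fell. Of 19 hypoxia genes 11 were higher and 1 lower (median log2 fold change 0.62, adjusted p = 0.00427, and adjusted p = 0.850 with an estimated correlation), with Epas1 (3.54) and Ankrd37 (1.78) up, both below 3 CPM, and Ndrg1 (-0.94) down. Of 5 mesothelial and epithelial markers 4 were lower and 0 higher (median log2 fold change -2.61, adjusted p = 9.81e-04, and adjusted p = 0.346 with an estimated correlation), led by the keratin Krt8 (-4.45) and Wt1 (-3.91).

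Of 28 cell cycle genes 15 were higher in KO at day 14 and 5 lower (median log2 fold change 0.69, adjusted p = 0.0209, and adjusted p = 0.937 with an estimated correlation), with Tyms (2.14) and Mcm5 (1.73) of DNA replication up and the mitotic Ube2c (-0.95) and Aurka (-0.63) down. The list did not pass without WT replicate 2 (0.0850) or 3 (0.104), or with fry (0.117). Of 17 genes of cholesterol synthesis 10 were higher and 0 lower (median log2 fold change 0.68, adjusted p = 0.0209, and adjusted p = 0.937 with an estimated correlation), with Fdps (1.67) and Stard4 (1.25) in front. This list did not pass with fry (0.113), without KO replicate 1 (0.0624) or without WT replicate 1 (0.0904, mean log2 fold change 0.30 against 0.73), and Fdps (0.0130) not without KO replicate 1 (0.0582). The interferon list, with 8 higher and 6 lower of 23, passed without KO replicate 1 alone (0.0105 against 0.204). Aldoc lost its call without KO replicate 1 (0.0640), and Hk2 (0.101, 0.0946) and Sesn1 (0.0581, 0.0693) without KO replicates 2 and 3. Without WT replicate 1, Sesn1 stood at 0.47 and Epas1 at 5.75. Adjusted over the list alone, the numbers higher and lower were 14 and 2 for glycolysis, 11 and 2 for hypoxia, 15 and 4 for the matrix, 11 and 0 for cholesterol synthesis and 10 and 6 for interferon, and the same as above for the other lists called.

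**Figure D4:**
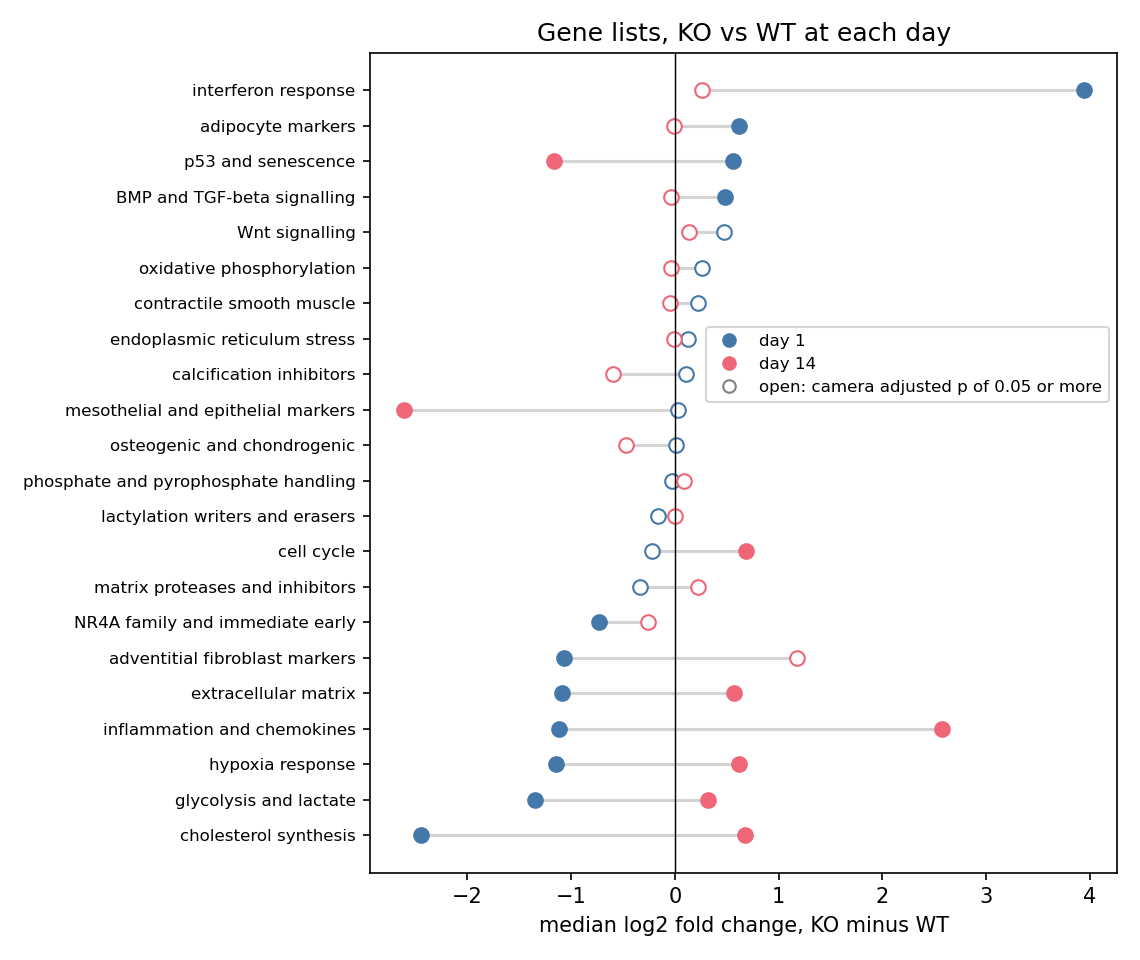
Median log2 fold change of KO against WT for each tested gene list at day 1 and at day 14; filled points are lists with a camera adjusted p below 0.05. The interferon list lies at 3.94 at day 1, and the inflammation list at -1.12 at day 1 and 2.58 at day 14.

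Of the calcification genes, the inhibitors Mgp and Enpp1 were higher in KO at day 14, with Mgp at 41.3 ± 4.88 CPM in KO and 1.17 ± 0.182 CPM in WT, and Enpp1 at 232 ± 8.57 and 7.65 ± 4.63 CPM (4.93 ± 0.41, adjusted p = 2.65e-05). Spp1 was higher too, with 3149.6 ± 203 and 499 ± 41.8 CPM (2.66 ± 0.10, adjusted p = 4.95e-07). Alpl (-3.75 ± 0.36), Msx2 (-4.73 ± 0.52), Sox9, a regulator of cartilage (-1.15 ± 0.21), Tnfrsf11b, the decoy receptor osteoprotegerin (-2.24 ± 0.35), and the phosphatase Phospho1 (-1.93 ± 0.43) were lower (adjusted p at most 0.00580). Acta2 (1.29 ± 0.14), Ldha (1.22 ± 0.12) and Pfkl (1.23 ± 0.20) were higher (adjusted p at most 9.90e-04). Cnn1, below 3 CPM, passed at 1.66 ± 0.47 (adjusted p = 0.0173) but not without KO replicate 1 (0.0870) or 3 (0.0586). Aldoa (0.28 ± 0.15, adjusted p = 0.152) and Runx2 (-0.41 ± 0.17, 0.0805) did not pass, and stood at 0.10 without WT replicate 1 and -0.23 without WT replicate 3. Runx2 passed without WT replicate 1 (-0.62, adjusted p = 2.28e-06), with library size alone (0.0473), without a filter (0.00379) and in the fit of 12 libraries (0.0269), and Aldoa in the last 2 of these settings (0.0180 and 0.0453).

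The KO effects of the 2 days ran in opposite directions for most of the genes called at both. Across 14503 genes the log2 fold changes correlated at Pearson r = -0.547 (Spearman rho = -0.467), a description across genes, which are not independent replicates. Of 4732 genes called at both days, 3883 (82.1%) had opposite signs and 849 the same sign. Higher in KO at day 1 and lower at day 14 were 2002 genes, where independent lists would share 1081, and the reverse held for 1881 genes, against 995 for independent lists. Higher at both days were 412 genes (1029 for independent lists) and lower at both 437 (1045).

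**Figure D5:**
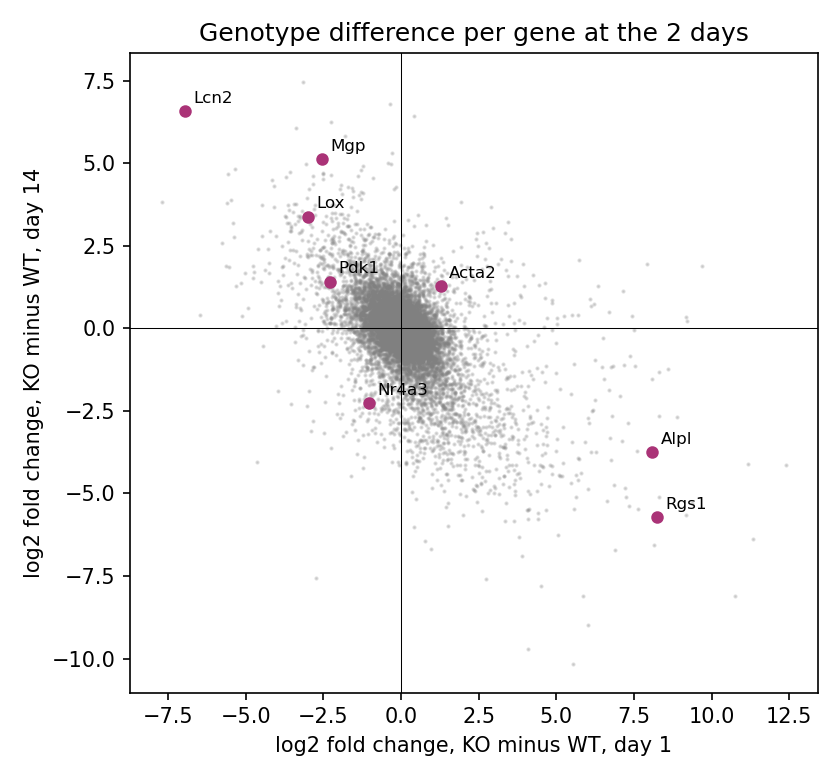
Log2 fold change of KO against WT at day 14 (vertical axis) against that at day 1 (horizontal axis) for 14503 genes, 1 point per gene, with some named genes marked. The points run from upper left to lower right (Pearson r = -0.547), and Nr4a3 lies at -1.02 and -2.27.

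The test of the change of the KO effect asks which differences of KO from WT changed between the days. Time in culture cannot be told apart here from a difference in cell population or labels particular to 1 genotype in 1 table. The secreted factor Stc1 stood at 76.1 ± 5.75 CPM in WT and 1.54 ± 0.756 in KO at day 1, and at 2.79 ± 1.54 and 72.2 ± 23.0 CPM at day 14 (SD, n = 3). Rgs1 went the other way, with 0.105 ± 0.0641 CPM in WT and 32.7 ± 6.17 in KO at day 1, and 38.5 ± 3.94 and 0.721 ± 0.446 CPM at day 14. The level of both in KO at day 1 lay near that in WT at day 14. The KO effect on cholesterol, glycolysis, hypoxia, matrix and inflammation genes was higher at day 14, and that on interferon and p53 genes lower. None of these lists kept its call with an estimated correlation (adjusted p from 0.0900 to 0.213).

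In all, 9597 of 15976 genes had a KO effect that differed between the days, 4716 of them higher and 4881 lower at day 14. The higher share was 49.1%, and 37.9% with library size alone, which shifts the median of all genes by -0.21. Among known genes with a mean log2 CPM of at least 3, some of the largest rises of the KO effect were those of Lcn2 (13.54 ± 0.71), Stc1 (10.30 ± 0.50), Hp (9.48 ± 0.77) and the receptor gene Calcrl (8.30 ± 0.24). Within this limit, the largest falls were those of Slc6a12 (-16.36, a fitted value against a group with 0 counts that depends on the prior count), Rgs1 (-13.92 ± 0.42), the glutamyl transferase Ggt1 (-12.02 ± 0.41) and Prr9 (-11.86 ± 0.51). Their adjusted p was at most 5.13e-08. Among the genes of calcification, smooth muscle and glycolysis followed in every comparison, the KO effect rose for Mgp (7.69), Enpp1 (6.17), Spp1 (3.87), Pfkl (2.99), Ldha (2.62) and Aldoa (1.93). It fell for Alpl (-11.79), Msx2 (-7.28), Myh11 (-4.09), Phospho1 (-2.75), Tnfrsf11b (-2.72) and Sox9 (-1.51), with adjusted p at most 0.00134. It was 0.03 ± 0.16 for Acta2 (adjusted p = 0.901), 0.19 ± 0.76 for Cnn1 (0.842) and 0.24 ± 0.20 for Runx2 (0.302), none called. With 1 library left out, Acta2 went from -0.13 without WT_day14 replicate 1 to 0.09 without KO_day14 replicate 3. Cnn1 went from -0.24 without WT_day14 replicate 3 to 0.61 without WT_day14 replicate 2, and Runx2 from 0.02 without WT_day14 replicate 1 to 0.39 without WT_day14 replicate 3.

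Of the lists, 18 of 18 cholesterol genes had a higher KO effect at day 14 (median log2 fold change 2.78, adjusted p = 3.30e-11; adjusted p = 0.213 with an estimated correlation). Among them was Fdps (5.95). Inflammation genes followed with 17 higher and 1 lower of 19 (median log2 fold change 3.16, adjusted p = 7.18e-16; adjusted p = 0.131 with an estimated correlation), with Nos2 (10.17) and Ccl5 (-2.02) beside Lcn2. For glycolysis 19 were higher and 2 lower of 24 (median log2 fold change 1.73, adjusted p = 1.07e-08; adjusted p = 0.192 with an estimated correlation). Among them were Pdk1 (3.71), Ldhb (-1.12) and Hk2 (-0.78). For hypoxia 16 were higher and 1 lower of 19 (median log2 fold change 1.71, adjusted p = 1.42e-07; adjusted p = 0.192 with an estimated correlation). Members included Ankrd37 (4.66), Epas1 (4.57) and Ndrg1 (-0.62). For the matrix 19 were higher and 5 lower of 27 (median log2 fold change 1.69, adjusted p = 3.31e-11; adjusted p = 0.213 with an estimated correlation). Among them were Lox (6.41), Col6a2 (5.58), Col11a1 (-5.39) and Postn (-4.69). For the cell cycle 16 were higher and 3 lower of 28 (median log2 fold change 0.70, adjusted p = 0.0214; adjusted p = 0.807 with an estimated correlation). Members included Tyms (2.64), Mcm6 (1.96), Aurka (-0.61) and Cdc20 (-0.51).

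The KO effect on interferon genes was lower at day 14 in 19 and higher in 1 of 23 (median log2 fold change -4.07, adjusted p = 7.18e-16; adjusted p = 0.162 with an estimated correlation), with Usp18 (-8.64) and Oas1a (-7.53) against Gbp2 (1.63). Usp18 stood at 27.0 ± 5.90 CPM in KO at day 1, 86.9 ± 20.9 in WT at day 14 and 39.3 ± 8.24 in KO at day 14. For p53 genes 15 were lower and 3 higher of 18 (median log2 fold change -1.56, adjusted p = 1.37e-07; adjusted p = 0.0900 with an estimated correlation). Among them were Phlda3 (-3.61), Btg2 (-3.34), Fas (3.09) and Sesn1 (1.68). For BMP and TGF-beta signalling 11 were lower and 7 higher of 22 (median log2 fold change -0.53, adjusted p = 0.00550; adjusted p = 0.213 with an estimated correlation). Members included Id4 (-9.57), Smad9 (-8.12), Ltbp2 (1.63) and Bmpr1b (6.03). Adventitial markers had 8 higher and 2 lower of 11 (median log2 fold change 1.99, adjusted p = 0.00731; adjusted p = 0.371 with an estimated correlation), with Serping1 (6.73), Cd34 (-1.49) and Dcn (-0.72); Dpt, without a count in KO at day 1, had a fitted 12.06. Mesothelial markers had 0 higher and 3 lower of 5 (median log2 fold change -2.19, adjusted p = 0.0414; adjusted p = 0.216 with an estimated correlation). Among them were Krt8 (-6.26) and Wt1 (-2.72). This list did not pass without KO replicate 3 of day 1 (0.0560) or of day 14 (0.0521), without WT replicate 2 of day 14 (0.0539) or with library size alone (0.0560). Wt1 (adjusted p = 0.0241) did not pass without KO replicate 3 of day 1 (0.0873) or KO replicates 1 and 3 of day 14 (0.0638 and 0.0527), and neither it nor Dcn passed with limma-voom (0.131 and 0.0890). Of the fits that leave out 1 library, Dcn (0.0414) passed only in those without KO replicate 2 or WT replicate 3 of day 1 or WT replicate 1 of day 14; without KO replicates 1 and 3 and WT replicates 1 and 2 of day 1 the values were 0.0559, 0.131, 0.0787 and 0.0850, and without KO replicates 1, 2 and 3 and WT replicates 2 and 3 of day 14 0.0523, 0.0927, 0.0505, 0.0680 and 0.0922. NR4A and immediate early genes (0.107) passed without KO replicate 1 (0.0468) or 2 (0.0497) of day 14, and calcification inhibitors (0.107) without WT replicate 1 of day 14 (0.0496), in a test that pointed up while the mean was -0.23, so no direction is given. Adjusted over the list alone, the called lists had the same counts except 6 lower for the matrix, 17 higher for the cell cycle and 8 higher for BMP and TGF-beta signalling.

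Between the days, WT libraries gained the interferon response and lost cholesterol, hypoxia and glycolysis transcripts. Of these lists only interferon kept its call with an estimated correlation (adjusted p = 0.00818, and 0.179 for the others). Oas2 rose from 3 counts in all at day 1 to 92.5 ± 9.41 CPM at day 14 (SD, n = 3), a ratio of 2362-fold (95% counting interval 808 to 11458, adjusted p = 4.92e-12), and Oas1g from 1 count, a ratio of 2063-fold (370 to 81557; fitted 10.41), though reads of its near-identical copies may be split. Alpl rose from 3 counts to 14.3 ± 5.49 CPM, a ratio of 364-fold (124 to 1771; fitted 8.30), and Slc6a12 from 0 counts, at least 542-fold (fitted 11.70). Col3a1 fell from 4338 ± 81.3 to 715 ± 192 CPM. The question is what the culture changes in cells with NR4A3, but the 2 days come from separate tables.

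In WT 8293 of 15976 genes differed between the days, 4119 higher and 4174 lower at day 14. The higher share was 49.7%, and 62.7% with library size alone, which shifts the median of all genes by 0.13. Usp18 (9.19 ± 0.36) was also among the largest rises, and the largest falls of known genes with a mean log2 CPM of at least 3 and no overlap between the groups were those of the calcium pump Atp2a3 (-5.51 ± 0.42), Phex (-5.35 ± 0.19), Rnf150 (-4.87 ± 0.28) and Stc1 (-4.77 ± 0.34), with adjusted p at most 4.37e-08. Of the genes of calcification, smooth muscle and glycolysis followed in every comparison, Msx2 (3.40), Myh11 (2.59) and Acta2 (1.26) rose. Mgp (-4.39), Spp1 (-1.33), Aldoa (-0.98), Ldha (-0.92) and Pfkl (-0.60) fell. The adjusted p of these rises and falls was at most 0.00377, and Pfkl stood at -0.36 without WT replicate 1 of day 14. Sox9 (0.61, adjusted p = 0.0214) did not pass without WT replicate 1, 2 or 3 of day 1 (0.0534, 0.0637, 0.0554) or WT replicate 1 of day 14 (0.31, 0.0950). Tnfrsf11b (0.70, 0.0464) did not pass without WT replicate 1, 2 or 3 of day 1 (0.0542, 0.110, 0.157), or without KO or WT replicate 1 of day 14 (0.0505, 0.128). Phospho1 (1.18, 0.0231) did not pass without WT replicate 1 or 3 of day 1 (0.0522, 0.118) or WT replicate 3 of day 14 (0.102). Without a filter, neither Tnfrsf11b (0.0640) nor Phospho1 (0.0525) passed, and Runx2 did (0.0147). Runx2 (-0.34, 0.0528), Enpp1 (-0.34, 0.376) and Cnn1 (1.21, 0.0722) did not pass, but did without WT replicate 3 of day 14 (0.00474, 0.0340 at -0.81, and 0.0166). Cnn1 also passed with library size alone (0.0478), and stood at 0.80 without WT replicate 2 of day 14. Without WT replicate 1 of day 14, Runx2 stood at -0.13 and Enpp1 at 0.12.

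In WT all 23 interferon genes were higher at day 14 (median log2 fold change 5.12, adjusted p = 3.05e-73, and adjusted p = 0.00818 with an estimated correlation), with Oas1a at 8.67 beside Usp18. No other list kept its call with an estimated correlation. All 18 cholesterol genes were lower (median log2 fold change -1.73, adjusted p = 8.78e-13; adjusted p = 0.179 with an estimated correlation). Fdps was among them (-3.18). Lower and higher were 20 and 2 of 24 glycolysis genes (median log2 fold change -0.87, adjusted p = 1.13e-06; adjusted p = 0.179 with an estimated correlation). Members included Aldoc (-2.43), Slc2a3 (-2.28), Ldhb (0.95) and Hk2 (0.72). Lower and higher were 15 and 0 of 19 hypoxia genes (median log2 fold change -0.99, adjusted p = 2.27e-06; adjusted p = 0.179 with an estimated correlation). Among them were Ero1l (-2.53) and Ankrd37 (-2.15). Lower and higher were 18 and 6 of 27 matrix genes (median log2 fold change -0.75, adjusted p = 4.78e-07; adjusted p = 0.333 with an estimated correlation). Members included Col6a3 (-2.76), Col3a1 (-2.60), Postn (5.31) and Col11a1 (1.87). Lower and higher were 9 and 1 of 11 adventitial markers (median log2 fold change -1.08, adjusted p = 0.00172; adjusted p = 0.333 with an estimated correlation). Members included Pi16 (-4.05) and Ly6a (0.44). Dpt fell from 46 counts to 1, a ratio of 32.4-fold (5.54 to 1309; fitted -4.63).

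Higher and lower at day 14 in WT were 10 and 5 of 18 contractile genes (median log2 fold change 0.53, adjusted p = 0.0276; adjusted p = 0.758 with an estimated correlation). Among them were Myl9 (4.25), Kcnmb1 (-2.21) and Vcl (-0.63). Lmod1 rose from 0.627 ± 0.116 to 10.1 ± 5.64 CPM. Higher and lower were 13 and 3 of 22 genes of BMP and TGF-beta signalling (median log2 fold change 0.92, adjusted p = 1.13e-06; adjusted p = 0.0763 with an estimated correlation). Members included Id4 (4.72), Smad9 (4.42), Bmpr1b (-3.21) and Ltbp1 (-0.75). Higher and lower were 10 and 1 of 18 p53 genes (median log2 fold change 0.40, adjusted p = 6.97e-04; adjusted p = 0.179 with an estimated correlation). Members included Phlda3 (2.08), Btg2 (1.28) and Sesn1 (-0.84). Inflammation genes were higher in 10 and lower in 4 of 19 (median log2 fold change 0.66, adjusted p = 0.0138; adjusted p = 0.607 with an estimated correlation). Members included Ccl5 (4.95), Saa3 (2.05), Lcn2 (-3.57) and Nos2 (-3.32). All 5 adipocyte markers were higher (median log2 fold change 0.89, adjusted p = 6.97e-04; adjusted p = 0.179 with an estimated correlation). Among them were Fabp4 (6.39) and Lpl (2.12). The cell cycle list (0.0587, with 14 lower and 1 higher) passed without WT replicate 2 of day 1 (0.0302), KO replicate 2 or 3 of day 14 (0.0493, 0.0469) or WT replicate 1 of day 14 (1.27e-05). Adjusted over the list alone, the numbers higher and lower were 11 and 5 for contractile genes, 1 and 15 for hypoxia, 7 and 19 for the matrix and 13 and 4 for BMP and TGF-beta signalling, and the same as above for the other lists called.

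In KO, inflammatory genes were far higher at day 14 than at day 1. The acute phase protein Saa3 rose from 0.306 ± 0.248 to 421 ± 131 CPM (SD, n = 3; 10.34 ± 0.32), Lcn2 from 0.0673 ± 0.0738 to 77.6 ± 40.8 CPM (9.98 ± 0.55), Hp from 0.158 ± 0.0427 to 51.4 ± 19.4 CPM (8.28 ± 0.53) and the neutrophil chemokine Cxcl5 from 18.8 ± 1.47 to 1794 ± 209.6 CPM (6.58 ± 0.13). Among known genes with a mean log2 CPM of at least 3 and no overlap between the groups, the largest falls were those of Stmn4 (-6.42 ± 0.24), Cd24a (-5.81 ± 0.19), Rgs1 (-5.47 ± 0.27) and the adhesion receptor Adgrg7 (-5.39 ± 0.16). These 8 genes had adjusted p of at most 5.73e-09, and in all 8762 of 15976 genes differed, 4303 higher and 4459 lower (49.1% higher, and 42.2% with library size alone). Of the genes of calcification, smooth muscle and glycolysis followed in every comparison, Enpp1 (5.84), Mgp (3.30), Spp1 (2.54), Pfkl (2.40), Ldha (1.70), Acta2 (1.29) and Aldoa (0.95) rose. Msx2 (-3.89), Alpl (-3.49), Tnfrsf11b (-2.02) and Sox9 (-0.90) fell. The adjusted p of these rises and falls was at most 0.00235. Runx2 stood at -0.10 ± 0.14 (adjusted p = 0.589), from -0.17 without KO_day1 replicate 2 to -0.04 without KO_day1 replicate 3. Cnn1 (1.40, 0.0150) did not pass without KO replicate 1 or 3 of day 1 (0.0632, 0.0625) or KO replicate 1 of day 14 (0.0790), and Phospho1 (-1.57, 0.0106) not without KO replicate 3 of day 14 (0.0644). Myh11 (-1.50, 0.0525), below 1 CPM, passed without KO replicate 2 of day 14 (0.0489) or with library size alone (0.0420).

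In KO the inflammation list was higher at day 14 in 18 and lower in 0 of 19 genes (median log2 fold change 4.09, adjusted p = 1.92e-48, and adjusted p = 0.0101 with an estimated correlation), and the p53 list lower in 15 and higher in 3 of 18 (median log2 fold change -1.21, adjusted p = 1.19e-07, and adjusted p = 0.0496 with an estimated correlation). Members included Eda2r (-2.20), Btg2 (-2.06), Fas (3.08) and Trp53 (0.91). Higher and lower were 18 and 2 of 23 interferon genes (median log2 fold change 1.14, adjusted p = 6.87e-11; adjusted p = 0.314 with an estimated correlation). Members included Gbp2 (4.94), Mx1 (4.58), Oasl1 (-1.82) and Rsad2 (-0.48). Higher and lower were 19 and 3 of 27 matrix genes (median log2 fold change 0.94, adjusted p = 3.03e-09; adjusted p = 0.319 with an estimated correlation). Among them were Lox (4.29), Col6a2 (3.11), Col11a1 (-3.52) and Dcn (-1.74). Higher and lower were 17 and 1 of 24 glycolysis genes (median log2 fold change 0.75, adjusted p = 3.75e-06; adjusted p = 0.314 with an estimated correlation), with Pdk1 at 2.38 beside Pfkl, and 16 and 1 of 19 hypoxia genes (median log2 fold change 0.79, adjusted p = 8.01e-05; adjusted p = 0.319 with an estimated correlation). Members included Epas1 (3.19), Ankrd37 (2.51) and Ndrg1 (-1.15). Slc2a3 fell from 17 counts to 1, a ratio of 14.8-fold (95% counting interval 2.32 to 618; fitted -3.54, adjusted p = 0.0113), with a fitted -5.65 without KO replicate 1 of day 14 and no call without replicate 3 (0.0557).

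Of 18 cholesterol genes 17 were higher and 1 lower at day 14 in KO (median log2 fold change 1.14, adjusted p = 1.91e-05; adjusted p = 0.510 with an estimated correlation). Fdps was among those higher (2.77). NR4A and immediate early genes were higher in 11 and lower in 6 of 19 (median log2 fold change 0.44, adjusted p = 0.0318; adjusted p = 0.477 with an estimated correlation), with Egr3 (3.96), Egr1 (3.63), Dusp1 (-2.33) and Atf3 (-2.00), but the list did not pass without KO replicate 1 or 3 of day 1 (0.0888, 0.0601) or WT replicate 1 of day 14 (0.0552). Mesothelial and epithelial markers were lower in 4 and higher in 1 of 5 (median log2 fold change -2.29, adjusted p = 0.00254; adjusted p = 0.189 with an estimated correlation), with Krt8 (-3.80), Krt19 (-2.67) and Krt7 (1.42), where Krt7 (0.0190) did not pass without KO replicate 1 or 2 of day 1 (0.0628, 0.0636) or KO replicate 3 of day 14 (0.0526). Calcification inhibitors (0.0669) passed without KO replicate 2 of day 1 (0.0487), KO replicate 1 or 2 of day 14 (0.0243, 0.0271) or WT replicate 1 of day 14 (0.00188), but with all libraries their test pointed up while the median was -0.12, so no direction is given. The cell cycle list (0.0669) passed without KO replicate 2 of day 1 (0.0463), KO replicate 3 of day 14 (0.0238) or WT replicate 1 of day 14 (0.00613), and adventitial markers (0.129) without KO replicate 2 of day 14 (0.0477). Adjusted over the list alone, the called lists had the same counts.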

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

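The tests of a shift between the tables and of a constant share of intact cells, and the 2 conditions put on crossed labels besides the share of blocks, were chosen only after the result was seen. Of 93 genes named for KO against WT at a day or for the change of that effect, 87 had an effect of KO that differed between day 1 and day 14 in the test of that difference (adjusted p below 0.05). Of these, 56 were called at both days with opposite signs and 9 with the same sign, and 22 were not called, or not tested, at 1 or both of the days. Values are the KO effect at day 14 minus that at day 1 (log2).

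Among genes lower in KO at day 1 and higher at day 14, the largest differences were those of Lcn2 (13.54), Stc1 (10.30), Nos2 (10.17), Hp (9.48), Calcrl (8.30), Rnf150 (8.15), Mgp (7.69), Clca2 (7.64), Egr3 (7.21), Serping1 (6.73) and Cd248 (6.67). Next came Phex (6.53), Lox (6.41), Abca1 (6.33), Enpp1 (6.17), Fdps (5.95), Col6a2 (5.58), Col3a1 (5.27), Ankrd37 (4.66), Nr4a2 (4.18), Spp1 (3.87) and Stard4 (3.76). The smallest were Pdk1 (3.71), Fas (3.09), Pfkl (2.99), Slc2a1 (2.93), Tyms (2.64), Ldha (2.62), Mcm6 (1.96), Sesn1 (1.68) and Trp53 (1.01). Higher in KO at day 1 and lower at day 14 were Slc6a12 (-16.36), Rgs1 (-13.92), Il7r (-13.58), Ggt1 (-12.02), Prr9 (-11.86), Alpl (-11.79), Id4 (-9.57), Stmn4 (-9.45) and Dthd1 (-9.43). These were followed by Usp18 (-8.64), Smad9 (-8.12), Cck (-8.11), Msx2 (-7.28), Ppargc1a (-6.84), Fabp4 (-6.61), Cd24a (-6.43), Krt8 (-6.26) and Col11a1 (-5.39). The differences of Dusp1 (-3.78), Phlda3 (-3.61), Btg2 (-3.34), Eda2r (-2.73), Aen (-2.42), Myc (-1.55) and Hk2 (-0.78) were smaller. With the same sign at both days, the effect was higher at day 14 for Il1rn (1.92) and Gbp2 (1.63), and lower for Wt1 (-2.72), Cd34 (-1.49), Nr4a3 (-1.23), Dcn (-0.72), Ndrg1 (-0.62), Lpl (-0.55) and Ube2c (-0.49). Among genes not called or not tested at 1 or both of the days, it was higher at day 14 for Dpt (12.06), Mmp9 (7.18), Bmpr1b (6.03), Ccl11 (6.03), Apln (5.54), Scn7a (5.38), Epas1 (4.57), Mcm5 (1.96), Aldoa (1.93), Ltbp2 (1.63) and Ltbp1 (1.25), and lower for Oas2 (-8.77), Oas1a (-7.53), Postn (-4.69), Myh11 (-4.09), Phospho1 (-2.75), Tnfrsf11b (-2.72), Ccl5 (-2.02), Sox9 (-1.51), Ldhb (-1.12), Aurka (-0.61) and Cdc20 (-0.51). Among the gene lists, the mean KO effect was higher at day 14 for inflammation and chemokines (4.10), adventitial fibroblast markers (3.38), cholesterol synthesis (3.13), hypoxia response (1.96), extracellular matrix (1.83), glycolysis and lactate (1.46) and cell cycle (0.72). It was lower for interferon response (-3.64), mesothelial and epithelial markers (-2.63), BMP and TGF-beta signalling (-1.45) and p53 and senescence (-1.34). With an estimated correlation, 0 of these 11 lists was called, and the adventitial mean (median 1.99) includes Dpt, fitted at 12.06 against a group with 0 counts.

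The KO libraries of day 1 were closest to the WT libraries of day 14. A shift between the 2 tables common to both genotypes cancels in the KO effect of each day. Such a shift cannot give KO effects that correlate at -0.547 (jackknife SE 0.0465). Apart from that of Yap1, 11 blocks of 15 neighbouring genes had opposite medians at the 2 days, where shuffled orders reached at most 5. A genotype effect that turns round on genes placed at random would not give this. But shuffling also separates neighbours that are regulated together. The test therefore cannot decide on a turning genotype effect that acts on such neighbours. Genotype labels crossed in 1 of the tables cannot be told apart from the rest: of 38 blocks shifted at day 1, 86.8% had the opposite sign at day 14, which met the prediction as written, but shuffled orders gave a median of 85.7%, and Nr4a3 was lower in the libraries labelled KO at both days. A difference in cell population, such as selection of cells with altered chromosomes, stays open. Shared regulation of neighbouring families like the protocadherins and Hox-B genes stays open for their own blocks, but would not by itself reach along a chromosome. Along chromosome 5, most blocks had positive medians at day 1 and negative ones at day 14, largely smaller than the 0.5 counted here. The exceptions began at Fzd1, Selenoi, Rbpj and Tmem119 at day 1, and at Abcb1b and Srsf9 at day 14. On chromosome 10, too, most blocks had positive medians at day 1 and negative ones at day 14. On chromosome 6, most blocks from Elmod3 on had negative medians at day 14. These runs were seen after the data were examined and were not set against shuffled orders. Neither cause was tested, and no DNA data were used here.

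Reads of Nr4a3 remained in every KO library. A constant share of cells with an intact gene would leave the same share of the WT level at both days. This holds only if those cells expressed Nr4a3 at the level of that day's WT libraries. The KO effect on Nr4a3 differed between the days (edgeR, adjusted p = 0.00181). But KO libraries differed from WT in 9341 genes at day 1 and 6918 at day 14. Intact cells there may thus not express Nr4a3 at the WT level, so the test cannot decide on a constant share. A share that changed with culture, or reads from a part of the gene outside the removed stretch, could also leave reads, and neither was tested, since the labels do not give that part.

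Between 2 groups of 3 libraries there are only 10 splits, too few for a test. The real split gave 9341 genes for KO against WT at day 1, 6918 at day 14, 8293 for WT between the days and 8762 for KO between the days, in each case 1 of 10 with as many, and the highest other gave 0. For the change of the KO effect, 100 of 200 possible splits were drawn. The real split, with 9597 genes, was the only 1 with as many, and the highest other gave 5852, so a random division of the libraries within each day is argued against. Splits that mix the groups raise the spread within them, and the replicates may be technical. The result therefore says nothing on chance between cultures.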

How the results depend on the processing

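The setting without shifted runs of neighbouring genes was chosen only after the result was seen, and the other settings before. All 264 alternative counts of genes lay within 1.5 times the reported count, and the correlation of the KO effects ranged from -0.566 to -0.504 over 15 alternatives. Leaving out 1 library gave 8163 to 9991 genes for KO against WT at day 1, 5182 to 9209 at day 14, 9046 to 10504 for the change of the KO effect, 7107 to 9068 for WT between the days and 7612 to 10021 for KO. With 1 library left out, Nr4a3 ranged from -1.11 to -0.96 at day 1 and from -2.43 to -2.05 at day 14. With library size alone it stood at -0.896 at day 1. With the replicate number as a block the counts were 9090, 6716, 9400, 8047 and 8568. The residuals of KO and WT libraries with the same number at the same day correlated at only -0.023 to 0.051. The numbers thus did not pair KO with WT within a day, and pairing between the days was not examined. The block gave a call to Sox9 at day 1 (0.0361) and Runx2 in WT between the days (0.0246), to the contractile list at day 1 (just below the threshold) and to the cell cycle list in WT (0.0424) and KO (0.0413), and ended that of Phospho1 in WT (0.0621). Without shifted neighbour blocks 8450 genes differed at day 1, 6152 at day 14 and 7901 in KO between the days, and the correlation was -0.537. That setting kept blocks with medians smaller than 0.5 at both days, which include most of those on chromosomes 5 and 10. With an estimated correlation, 5 lists were called at day 1, 0 at day 14, 0 for the change of the KO effect, 1 in WT and 2 in KO between the days. Fry, which asks if a list moves at all and not more than other genes, called 19 at day 1, 18 for the change of the KO effect and 17 in KO between the days. The other 65 of 73 alternative list counts lay within 1.5 times the reported ones. Of 4704 alternative values of single genes 4626 kept their side of the threshold, 22 gained a call, 56 lost it and 0 reversed. Of 1656 for single lists 1551 kept it, 50 gained a call, 55 lost it and 0 reversed. The causes were not tested. Genes dropped by a stricter filter have no value there. Library depth limits genes with few counts, such as Nr4a3 at day 1 with 34 to 48 counts per KO library.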

Other observations

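No test of a hypothesis was run for this part, and the values in it were chosen only after the result was seen. The libraries held transcripts from the marker lists of other cell types, which do not by themselves show that such cells were present. Of the adventitial fibroblast markers, Gsn led at day 1 with 284 CPM in KO and 599 CPM in WT. At day 14 Ly6a led them with 612 CPM in KO and 546 CPM in WT. Endothelial markers were low, with a median of at most 0.458 CPM over the list and Cdh5, the junction protein VE-cadherin, between 3.84 CPM (KO, day 1) and 13.3 CPM (WT, day 1). The scavenger receptor gene Cd68 led the leukocyte markers with 50.3 CPM in KO at day 1, and 30.1 CPM in KO and 59.9 CPM in WT at day 14. In WT at day 1 Cd14 led with 38.8 CPM, and in every group the median of the leukocyte list was at most 0.0688 CPM. Lpl, the lipase of fat cells that is also made by macrophages, ranged from 99.2 CPM (WT, day 1) to 1057 CPM (KO, day 14). The mesothelial gene Msln stood at 352 CPM in KO and 317 CPM in WT at day 1, and at 75.5 CPM and 358 CPM at day 14. Mbp, a myelin gene, ranged from 1.52 CPM (KO, day 14) to 11.5 CPM (WT, day 14).

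Xist, the RNA that coats the inactive X chromosome, had 17930 to 48089 counts in all 12 libraries, and the Y-linked Ddx3y 0 or 1. Ribosomal protein transcripts took 3.40% ± 0.28 of the counts in KO and 2.46% ± 0.03 in WT at day 1 (SD, n = 3), and 1.94% ± 0.05 and 2.74% ± 0.05 at day 14. Besides the Yap1 block, 11 blocks of 15 neighbouring genes had opposite medians of at least 0.5 at the 2 days. Among them were those from Vipas39 to Gm18619 on chromosome 12 (KO against WT -1.54 at day 1 and 2.03 at day 14) and from Pcdhb21 to Hdac3 on chromosome 18 (-1.42 and 1.55). Another reached from Ngfr to Hoxb5os on chromosome 11 (0.76 and -0.52), in the order of GRCm38.p6. Smaller shifts ran along chromosomes 5 and 10, with positive medians at day 1 and negative ones at day 14 in most of their blocks. Within WT at day 14, replicate 1 differed from replicates 2 and 3 by a chi-square per gene of 36.2 and 51.5, and these differed from each other by 9.20.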
